A study of Drosophila melanogaster with 3 samples.

How the data were processed

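Chromatin immunoprecipitation and sequencing was done by the authors on whole wandering larvae of a line with GFP-tagged rgr, with sonicated chromatin and an antibody against GFP, per the labels. The labels number 3 biological replicates, which form 1 group. The analysis started from the peak lists the authors deposited on dm6 and dm3. Per the file listing, each replicate has a relaxed list called on its own alignment and a control alignment, a pooled list was called on the 3 replicate alignments with the same control, and the optimal dm6 list was derived from these by the irreproducible discovery rate. The aligner, the peak caller and the threshold are not given in the sources used here. For dm3 the listing names only the list of replicate 2 and the pooled list as the origin of the optimal list.

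The deposited peak signal has no stated scaling between lists, so it was used to rank peaks within a list. The authors' −log10 q-value reached the same maximum of 4.19 for 7820 peaks of the dm6 optimal list and was not used for ranking. The optimal list was identical to the 8551 peaks of highest signal in the pooled relaxed list. No list holds read counts, so depth is unknown and no interval depends on it. Intervals for shares of peaks are exact binomial ones at 95% and cover counting error only. The coordinates are dm6, 1-based, and dm3 lists were used only for counts and overlap because no dm3 annotation was used here. No column of per-sample values was left over.

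Genes and transcript starts came from Ensembl release 115 (BDGP6.54, dm6 coordinates) and sequence from the RefSeq copy of the same assembly, for arms 2L, 2R, 3L, 3R, 4, X and Y. A promoter peak has its summit within 500 bp of any annotated transcript start. A summit in several features was given to the first of promoter, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic sequence. Replicate lists were cut to their top 8551 peaks, and 2 summits matched within 100 bp. Chance values came from 100 random placements on the same chromosomes.

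The 31 gene lists and 29 words were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. The rule takes rgr, the nearest transcript start of each of the 20 optimal peaks with the highest signal, and up to 3 members with the highest promoter signal of each list that was called. Lists were tested with a two-sided Fisher's exact test of genes with a promoter peak against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists, called at 0.05. Genes are not independent replicates, and p-values do not measure variation between larvae. Names were matched by symbol or unique synonym. The cuticle list was defined by a name pattern and also took in the accessory gland genes Acp33A, Acp62F, Acp63F and Acp76A. Words were searched on both strands within 50 bp of the summit and in a window of the same width centred 300 bp to a seeded side, and compared with a two-sided exact McNemar test adjusted over the words.

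Alternatives were other matching and promoter distances, the peaks with the higher signal, another set of starts, another background, rotation along gene order, other windows, dm3 lists and leaving out each replicate. A replicate was left out by keeping the optimal peaks found in the top lists of both others (6138, 5919 and 6467 peaks without replicates 1, 2 and 3). Alternatives chosen after seeing the data were shuffled and AT-matched sequence as controls, peaks anywhere in the gene body against genes of similar length, and the peaks with the lower signal.

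The functions were tested on simulated data. With members of a list bound at 65%, the list test called the cell cycle list in 90 of 100 simulations, the Hippo list in 63 and the glial list in 54, so lists of that size can be missed. It called 0.286% of 2800 lists with nothing planted. A word planted in 1.74% of windows was recovered at 1.74%, and 75.3% planted sharing at 75.7%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.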

Results

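The data are binding profiles of rgr (regular), a Drosophila melanogaster protein assayed as a transcription factor. Chromatin was immunoprecipitated with an antibody against GFP from whole wandering larvae, males and females pooled, of a line that carries rgr with GFP at its carboxyl terminus. There was 1 group with 3 biological replicates, so the comparisons are between replicates, between stronger and weaker peaks, and between peaks and the rest of the genome. The authors called peaks on each replicate and on the 3 replicates pooled, each with a control alignment. Each of these relaxed lists held 30000 peaks, and the thresholded list (called optimal below) held 8551 peaks on dm6 covering 2.83 Mb. The pooled relaxed list is titled peaks and background, so entries called relaxed peaks below may be background. Peak lists carry no read counts, so the depth behind each list is unknown. Peak signal is the authors' own value and was used only to rank or describe peaks within a list.

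The 20 strongest peaks lay mostly at gene starts, 14 of them within 500 bp of an annotated transcript start. The strongest (signal 5263) was at 2L:6612708, in an intron 1021 bp from the nearest start, that of CG11050. The next (5191) was 91 bp from the start of CG14100, on 3L. The peak at 2L:481047 (5004) was 1359 bp from the start of cbt, which encodes the zinc finger factor cabut, and lay in an intron of the surrounding gene ush. Promoter peaks followed at Ugalt, a UDP-galactose transporter gene on X (4582, 36 bp from the start), and at PNPase, encoding polynucleotide phosphorylase, on 3R (3912, 81 bp). Other genes with one of the 20 peaks at the promoter were CenG1A, Tcs5, CG1888, CG8320, the chromatin protein gene Chro, the mitochondrial ribosomal protein gene mRpL41, the long noncoding RNA gene CR31044, the small heat shock gene Hsp27, the casein kinase gene gish, CG18549 and the potassium chloride cotransporter gene kcc. The peaks nearest to CG32772, the kinase gene Lk6 and CG16753 lay in introns 1259, 976 and 5717 bp from a transcript start, and that nearest to CG13323 was intergenic, 11907 bp away. All 20 were found within 100 bp in each replicate, at rank 36 or better in each of the 3 lists. They were picked from a list called on the same replicates pooled, so high ranks follow in part from the choice.

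The tagged gene itself carried several peaks. In rgr (2R:8600415 to 8612295, plus strand) 6 optimal summits fell within the gene. The first lay in the 5′ UTR, at 8600459, 44 bp from the transcript start (signal 311). The strongest was in the long intron at 8601379 (signal 622), at rank 956, 833 and 1064 in replicates 1, 2 and 3. The others were at 8603148 and 8607295 in the same intron, at 8608208 in a coding exon and at 8611463 in the 3′ UTR, where CG8642 overlaps from the other strand. The 3′ UTR peak was uneven between replicates, at rank 14331, 3796 and 27151. In a comparison added after seeing the data, the median count was 0 among 564 protein-coding genes within 1.2 times the length of rgr, and 8 of them (1.42%) had at least 6. The labels do not say whether the tag sits at this locus or in an added copy, so the peaks cannot be assigned to one or the other.

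**Figure D1:**
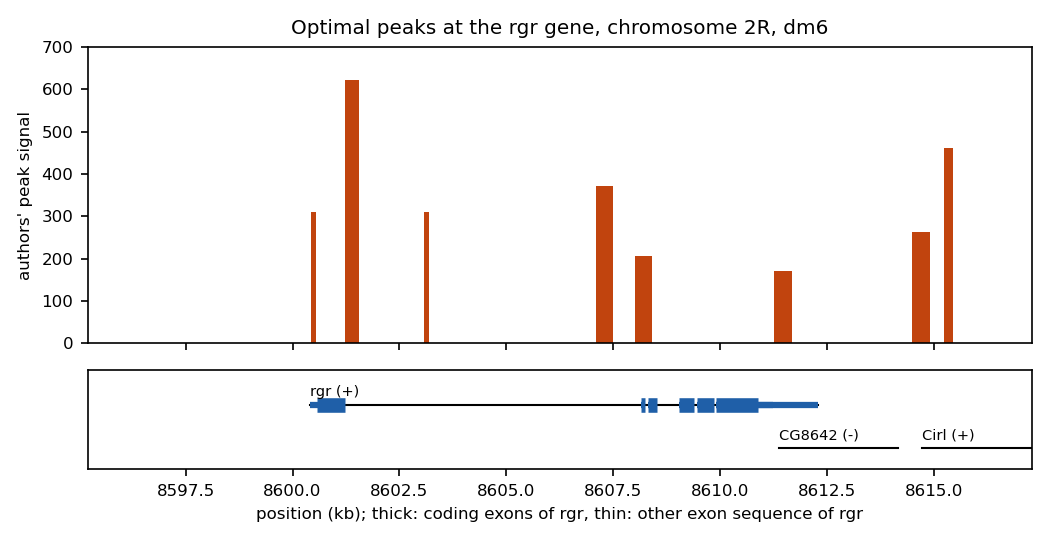
Optimal peaks at rgr and its neighbours on chromosome 2R. The horizontal axis is the position in kb on dm6 and bars span each peak, with height giving the authors' peak signal; the lower track shows rgr with its exons, CG8642 and the start of Cirl. The tallest bar, 622, is in the first intron of rgr.

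Replicates shared most of their strongest peaks. Of the top 8551 peaks of a replicate, 74.2% ± 2.52 (SD over 3 pairs) had a summit within 100 bp of a top peak of another replicate: 77.1% for replicates 1 and 2, 72.5% for 1 and 3, and 72.9% for 2 and 3. Summits placed at random on the same chromosomes shared 1.30% ± 0.0705 (SD, n = 100 placements) and at most 1.47%. Random placement ignores open chromatin, and all replicate lists were called against the same control, so part of the sharing need not come from rgr. The optimal peaks were themselves derived from these replicates, so the next values on them are in part fixed by that choice. Among the optimal peaks, 5544 (64.8%) were in the top lists of all 3 replicates, 1892 in those of 2, 997 in 1 and 118 in none. Across the optimal peaks found in both relaxed lists, which are not independent replicates, Spearman's rho of signal ranks was 0.847 for replicates 1 and 2, 0.806 for 1 and 3, and 0.815 for 2 and 3. The share depended on the matching distance, from 61.3% at 50 bp to 80.4% at 200 bp.

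Peaks were concentrated at promoters and nearly missing from coding sequence. Within 500 bp of a transcript start lay 3896 optimal summits, 45.6% (exact 95% interval 44.5% to 46.6%), against 13.6% ± 0.396 (SD) of summits placed at random 100 times. Across the 3 replicates the share was 46.8% ± 0.688 (SD, n = 3). Coding exons outside promoters held 20 summits (0.234%, against 13.7% of random positions) and 3′ UTRs 82 (0.959%, against 4.45%). Introns held 37.3%, close to the random 39.4%, and intergenic sequence 14.4% against 27.2%. The 21449 weaker relaxed entries outside the optimal list, which may include background, were at promoters in 23.7% of cases. The odds ratio was 2.70 for the optimal peaks (two-sided Fisher's exact test, p = 1.52e-293, with peaks not independent replicates). It does not compare strong with weak binding alone. The promoter share was 57.9% in the tenth of optimal peaks with the highest signal and 37.3% in the tenth with the lowest.

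Among the 31 gene lists, ribosomal protein genes most often had a promoter peak, though open chromatin was not measured. Shares in this and the other lists thus need not come from a choice of targets by rgr. A promoter peak was present at 77 of 94 ribosomal protein genes (81.9%), against 28.6% of other protein-coding genes (odds ratio 11.3, two-sided Fisher's exact test, adjusted p = 2.65e-25). The share was 81.9% ± 2.81 (SD, n = 3) over the replicates. The strongest were RpL7 on 2L (signal 1747, summit 33 bp from its start), RpS27 on 3R (1741, 6 bp) and RpL14 on 3L (1478, 59 bp). Translation initiation factor, proteasome and oxidative phosphorylation genes were not called: 17 of 44 (38.6%), 15 of 48 (31.3%) and 33 of 87 (37.9%) had a promoter peak. Taking only the 6395 genes with a relaxed peak at the promoter as the background, 77 of 80 ribosomal protein genes had an optimal peak against 62.9% of the rest (Fisher's exact test, adjusted p = 6.23e-11). In the 4275 optimal peaks with the higher signal 71.3% of ribosomal protein genes had a promoter peak (odds ratio 11.5, exact test, adjusted p = 5.43e-28). The 4276 with the lower signal, a set chosen after seeing the data, held one at 20.2% (odds ratio 1.61, not called), but the split had put most of these genes with the stronger peaks, so it is no test of the call.

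Genes of cell division, the Hippo growth pathway and chromatin boundaries also had promoter peaks more often than others. Peaks stood at 19 of 33 cell cycle and replication genes (57.6%, odds ratio 3.34, Fisher's exact test, adjusted p = 0.00284). The strongest were at dpa, which encodes an MCM helicase subunit (signal 785, 2R), the licensing factor gene dup (503, 2R) and the mitotic kinase gene aurA (478, 3R). Of the Hippo pathway genes 11 of 17 had a peak (64.7%, odds ratio 4.50, adjusted p = 0.00654 by Fisher's exact test): the kinase gene hpo (623, 2R), the tumour suppressor gene Mer (488, X) and yki, the transcriptional coactivator of the pathway (289, 2R), were the strongest, though replicate 2 had no summit within 100 bp of the yki peak. The Hippo call was lost among optimal peaks backed by the other replicates without replicate 1 (35.3%, odds ratio 1.84, exact test, adjusted p = 0.364) and without replicate 3 (41.2%, odds ratio 2.20, adjusted p = 0.258). These sets keep only optimal peaks found in both other top lists. In the own top lists of replicates 1, 2 and 3 the Hippo share was 64.7%, 58.8% and 58.8%, so the loss does not show that the call rests on replicate 1 or 3. Insulator and promoter-proximal factor genes had peaks at 11 of 18 (61.1%, odds ratio 3.86, adjusted p = 0.0158 by Fisher's exact test), led by Chro (3337, 3L), the insulator protein gene Cp190 (1209, 3R) and Trl, which encodes GAGA factor (752, 3L). None of these 3 lists was called against the 6395 genes with a relaxed peak at the promoter, with odds ratios of 2.21, 1.60 and 2.13 and adjusted p of 0.296, 0.665 and 0.413. Cell cycle and Hippo genes were not called in the 4275 peaks with the higher signal (odds ratios 1.96 and 2.46) but were in the 4276 with the lower signal (3.18 and 4.45, exact test, adjusted p = 0.0228 and 0.0249). Insulator genes were called with the higher signal (odds ratio 3.61, exact test, adjusted p = 0.0282) and not with the lower (1.81, adjusted p = 0.516), nor within 250 bp of a start (3.12, adjusted p = 0.0542). With peaks in the gene against genes of similar length, a test also chosen after seeing the data, none of the 3 was called, at 30.3% against 18.7%, 64.7% against 38.2% and 33.3% against 21.2% (permutation test, adjusted p = 0.340, 0.135 and 0.607).

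Chemosensory receptor, cuticle, digestive enzyme, P450, antimicrobial peptide, testis-specific, eggshell and neuronal genes had a promoter peak less often than other genes. Open chromatin at these genes was not measured. Only 16 of 229 receptor genes and 1 of 20 eggshell and yolk genes had even a relaxed peak at the promoter. Of odorant, gustatory and ionotropic receptor genes with the odorant-binding proteins, 5 of 229 (2.18%) had a promoter peak (odds ratio 0.0535, Fisher's exact test, adjusted p = 1.46e-25): Ir60e (418), Obp83g (300), Gr63a (206), Obp99b and Gr77a. Cuticle protein genes had 3 of 126 (2.38%, exact test, adjusted p = 7.11e-14), which were Cpr12A, Cpr66D and Cpr73D, with signals of 222, 185 and 173. Digestive enzyme genes had 2 of 60 (exact test, adjusted p = 3.16e-06), the maltase gene Mal-A5 (1090) and the trypsin gene kappaTry (141). Cytochrome P450 genes had 11 of 81 (13.6%, exact test, adjusted p = 0.00603), the strongest at Cyp6u1 (1167), Cyp6a2 (362) and Cyp317a1 (332), all on 2R. Antimicrobial peptide genes had 1 of 32, Drsl6 (150, exact test, adjusted p = 0.00168), at rank 12522 in replicate 1. Testis-specific genes had 3 of 45 (exact test, adjusted p = 0.00177), Mst85C (230), the meiotic phosphatase gene twe (185) and bol (159), and genes of the eggshell and yolk had 0 of 20 (adjusted p = 0.00603). Neuronal genes had 5 of 50 (10%, adjusted p = 0.00654 by the same exact test): elav, the RNA-binding protein gene of neurons, with a signal of 1288, Nrx-1 (258), the potassium channel gene sei (254), Csp and Appl. The genes Obp99b, Gr77a, Csp and Appl, and His3.3A below, are named although they fall outside the rule for named genes, and were added after their values were seen.

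Against the 6395 genes with a relaxed peak at the promoter, digestive enzyme, P450 and neuronal genes were called depleted (2 of 20, 11 of 37 and 5 of 20, odds ratios 0.0640, 0.243 and 0.192, Fisher's exact test, adjusted p = 1.59e-05, 0.000407 and 0.0046). Receptor, cuticle and antimicrobial genes were not called (5 of 16, 3 of 10 and 1 of 6, odds ratios 0.263, 0.248 and 0.116, exact test, adjusted p = 0.0748, 0.138 and 0.0976). Their odds ratios against all other genes were 0.0535, 0.0591 and 0.0788, so the depletion was weaker here, and on fewer genes. Testis genes were at 3 of 5 (odds ratio 0.870, not called), and eggshell and yolk genes were too few to test. Neuronal genes were not called within 1000 bp of a start (18%, odds ratio 0.448 against 0.271 within 500 bp, exact test, adjusted p = 0.0528). In the 4275 peaks with the higher signal their odds ratio was 0.287 and eggshell and yolk genes had 0 peaks, without a call for either (exact test, adjusted p = 0.0720 and 0.0948). In the 4276 with the lower signal, neuronal, P450, antimicrobial, testis-specific and eggshell and yolk genes were not called, at odds ratios of 0.263, 0.505, 0.204, 0.294 and 0 (exact test, adjusted p = 0.215, 0.293, 0.277, 0.227 and 0.254). With peaks in the gene against genes of similar length, only receptor and neuronal genes were called depleted. Cuticle genes were at 2.38% against 6.63%, digestive enzyme genes at 0% against 6.02% and P450 genes at 4.94% against 11.8%, not called (permutation test, adjusted p = 0.157, 0.158 and 0.158). These last 2 settings were added after seeing the data.

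Core histone genes had a peak at 4 of 115 (adjusted p = 1.90e-11, Fisher's exact test). These 4 lie outside the repeats described next: His2Av on 3R (516), His4r on 3R (261), His3.3B on X (252) and His3.3A on 2L (170). The other 111 are near-identical repeats between 2L:21416953 and 21541681, a span with 0 relaxed summits. Reads from such copies cannot be placed uniquely, so this low count is uncertain.

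The remaining 18 lists were not called. Polycomb and trithorax group genes had 15 of 31 (48.4%, adjusted p = 0.0599, Fisher's exact test), called only without replicate 3 (45.2%, adjusted p = 0.0248). Ecdysone response genes had 16 of 35 (45.7%, exact test, adjusted p = 0.0799), called within 1000 bp (62.9%, adjusted p = 0.00136). Patterning transcription factor genes had 13 of 63 (20.6%, exact test, adjusted p = 0.243) and were called depleted in the 4275 peaks with the higher signal (4.76%), against genes with a relaxed peak at the promoter (adjusted p = 0.00775), and without each replicate in turn. The other lists had a peak at 0 of 8 Hox genes, 2 of 22 salivary gland secretion genes, 3 of 21 hemocyte, 5 of 20 tracheal, 10 of 39 contractile muscle, 8 of 28 Notch pathway, 8 of 24 insulin and TOR, 6 of 18 glial, 5 of 14 circadian clock, 7 of 19 fat body, 14 of 36 Wnt, Hedgehog and Dpp, and 12 of 27 heat shock genes. In all, 4048 of 13968 protein-coding genes (29.0%) had a promoter peak, and a peak between divergent genes was counted for both. Rotating peak status along gene order, which keeps neighbouring genes together, kept all 13 calls.

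**Figure D2:**
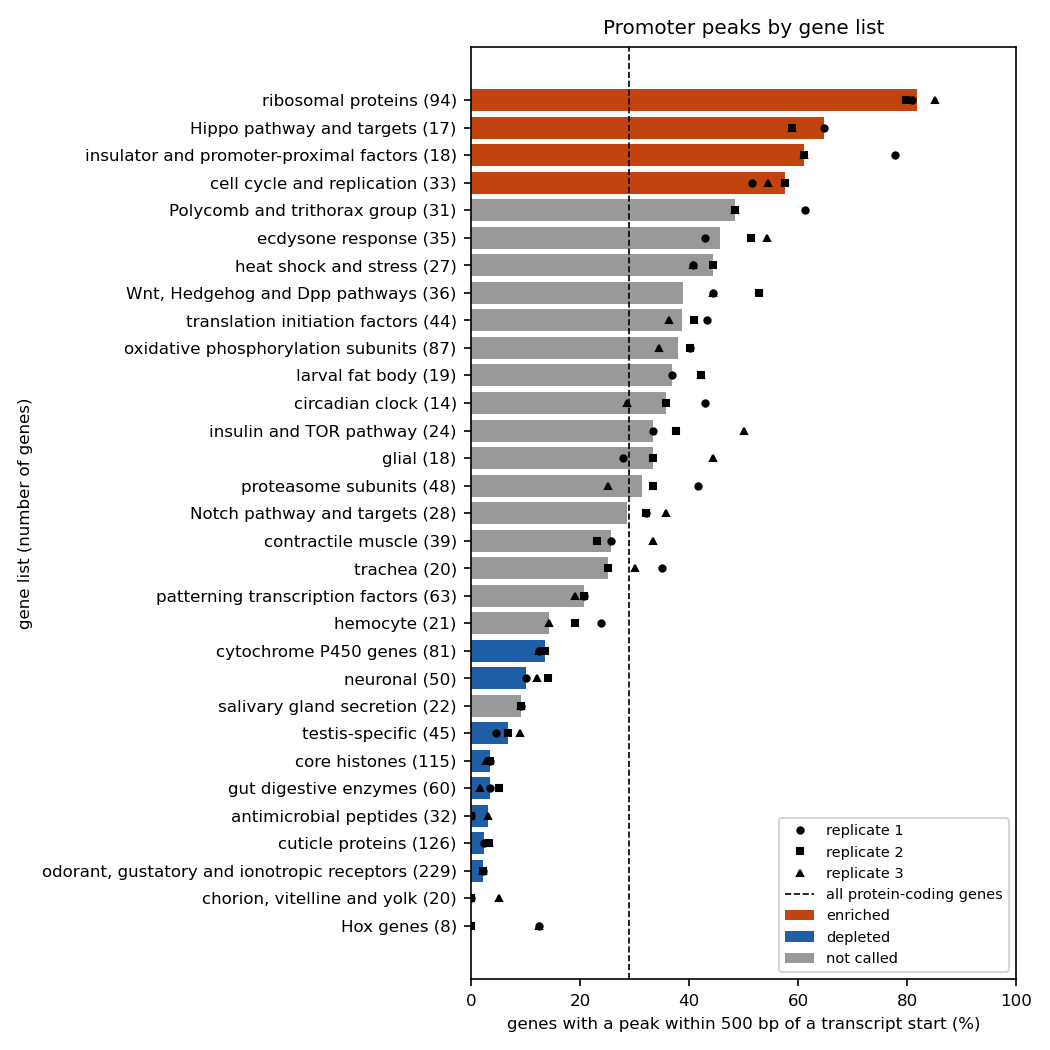
Share of genes with a peak within 500 bp of a transcript start for 31 gene lists, on an axis from 0 to 100%. Bars are the optimal list, coloured by the call of Fisher's exact test; points are the top 8551 peaks of each replicate, and the dashed line is all protein-coding genes (29.0%). Ribosomal proteins stand highest at 81.9%.

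Summits carried words of housekeeping promoters and AT-rich words more often than sequence 300 bp away. The DRE word TATCGATA, bound by DREF and BEAF-32, was within 50 bp of 1.88% of summits and in 0.281% of flanking windows, a ratio of 6.71 (two-sided exact McNemar test over 29 words, adjusted p = 6.07e-25). Over the replicates it was at 1.93% ± 0.300 of summits and 0.327% ± 0.0651 of flanks (SD, n = 3). The M1BP word GGTCACAC was at 1.5% against 0.398%, Ohler motif 7 at 2.85% against 1.27% and Ohler motif 6 at 3.98% against 2.33%. The TATA box word was at 8.38% against 4.13%, the Homeodomain word TAATTA at 8.53% against 5.70%, Forkhead at 3.44% against 2.63%, a run of 8 A at 7.75% against 6.60%, and the Su(Hw) core TGCATACTT at 0.398% against 0.0936%. These made 9 enriched words. The 7 depleted words were the CA repeat (1.63% against 3.99%), both GAGA words (1.72% against 2.89% for GAGAGAG), CACGTG, Zelda, Su(H) and Grainyhead, and 13 words were not called.

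At promoters the DRE word stood at 3.93% of the 3896 summits and 0.616% of flanks. Among the 4655 other summits it stood at 0.172% against 0.0430% and was not called (exact McNemar test, adjusted p = 0.179), and neither was Ohler motif 7 (adjusted p = 0.223). The Su(Hw) core was called away from promoters (0.580% against 0.172%) and not at them (0.180% against 0.128%, adjusted p = 0.774 by the exact McNemar test). Forkhead was likewise called away from promoters (3.61% against 2.30%) and not at them, where summits were below flanks (3.23% against 3.52%). The difference between the peak sets was not tested. Summit windows were 63.8% A or T, flanks 56.3% and the genome 57.9%, and over the replicates summits were 63.5% ± 0.589 and flanks 56.4% ± 0.0821 (SD, n = 3). The highest-ranked word of 6 bases was AAATAT, in 29.7% of summit and 15.5% of flanking windows. Against genomic windows of equal AT content, a control added after seeing the data, only 4 of the 9 words stayed enriched: DRE, M1BP, Ohler motif 7 and Forkhead. Not called against flanks but enriched against these windows were Ohler motif 5 (5.5 times), the dCTCF core (2.78 times) and the E-box word CAGCTG (1.66 times, exact McNemar test, adjusted p = 1.68e-09, 1.81e-11 and 2.65e-09), and all 3 were enriched against shuffled windows. At promoters the dCTCF core was also called against flanks (2.61 times). Away from promoters it was at 1.01 times its flank share and not called, and CAGCTG was called depleted against flanks (0.706 times, exact McNemar test, adjusted p = 0.00418). The direction of 5 depleted words turned against the AT-matched windows. GAGAGAG was at 2.58, GAGAG at 1.29 and the CA repeat at 1.43 times its share in such windows and each was called enriched (exact McNemar test, adjusted p = 1.38e-09, 5.46e-08 and 0.0195), while Su(H) at 1.06 and Grainyhead at 2.5 times were not called. CACGTG at 0.986 and Zelda at 0.865 times kept their direction but were not called, so no depleted word stayed depleted against AT-matched windows. Calls were also lost in other settings, some with little change of the ratio to flanks. Forkhead, at 1.31 times its flank share, was at 1.26 and 1.23 without replicates 2 and 3, and the A run, at 1.18, was at 1.15 without replicate 1 (adjusted p from 0.0635 to 0.0699, exact McNemar test). Within 25 bp of summits they were at 1.28 and 1.15 (exact McNemar test, adjusted p = 0.1 and 0.138). Without each replicate in turn Zelda stood at 0.6 to 0.645 against 0.582 with all, and Grainyhead at 0.353 to 0.429 against 0.385, and neither was called (exact McNemar test, adjusted p from 0.0915 to 0.259 and from 0.0631 to 0.209). Su(H), at 0.629, was at 0.681 and 0.695 without replicates 1 and 3 (exact McNemar test, adjusted p = 0.0871 and 0.0649). In the 4275 peaks with the higher signal Zelda, Su(H), Grainyhead and the Su(Hw) core were not called (ratios 0.515, 0.643, 0.3125 and 3.2), nor without promoter peaks Zelda and Grainyhead (0.576 and 0.455). Within 25 bp Zelda and Su(H) were not called (0.76 and 0.755), nor within 100 bp Su(H) and Grainyhead (0.848 and 0.578).

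**Figure D3:**
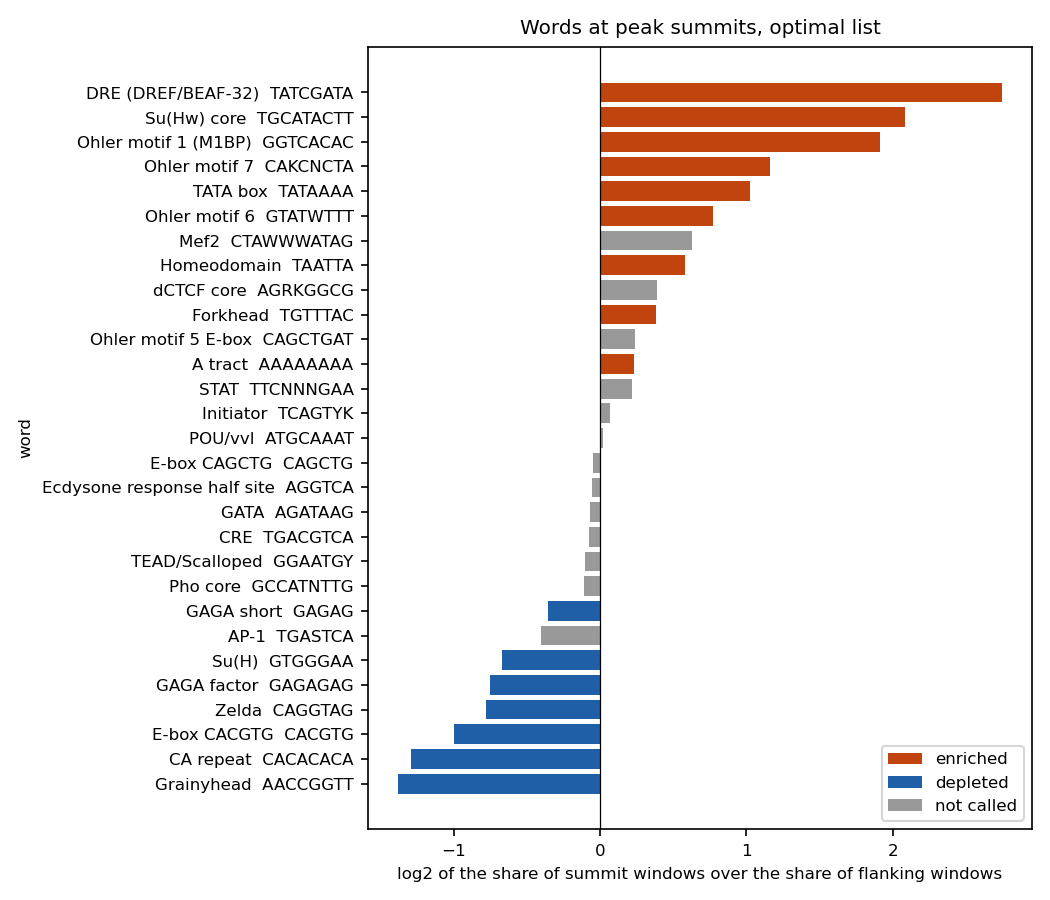
Words at summits of the 8551 optimal peaks. Bars give log2 of the share of windows within 50 bp of a summit holding the word over the share of windows centred 300 bp away, coloured by the exact McNemar test. DRE is at the top, 6.71 times as frequent at summits, and Grainyhead at the bottom.

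Peak density on X was close to that on the large autosome arms, but replicates differed. The optimal list had 65.2 peaks per Mb on X, and 65.9, 61.0, 68.1 and 62.0 on 2L, 2R, 3L and 3R, an X to autosome ratio of 1.02. Of the peaks on these arms 18% were on X (exact 95% interval 17.2% to 18.8%), which holds 17.8% of their length. The ratio was 1.08, 0.991 and 0.906 in the top lists of replicates 1, 2 and 3 (mean 0.992 ± 0.0870, SD, n = 3). The share of top peaks on X was 18.9% in replicate 1 (exact interval 18% to 19.7%) and 16.3% in replicate 3 (15.5% to 17.1%), intervals that do not overlap and that cover counting error only. Counted per protein-coding gene the ratio was 1.17. Chromosome 4 had 22 optimal peaks (16.3 per Mb), and Y had 0 in every list.

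**Figure D4:**
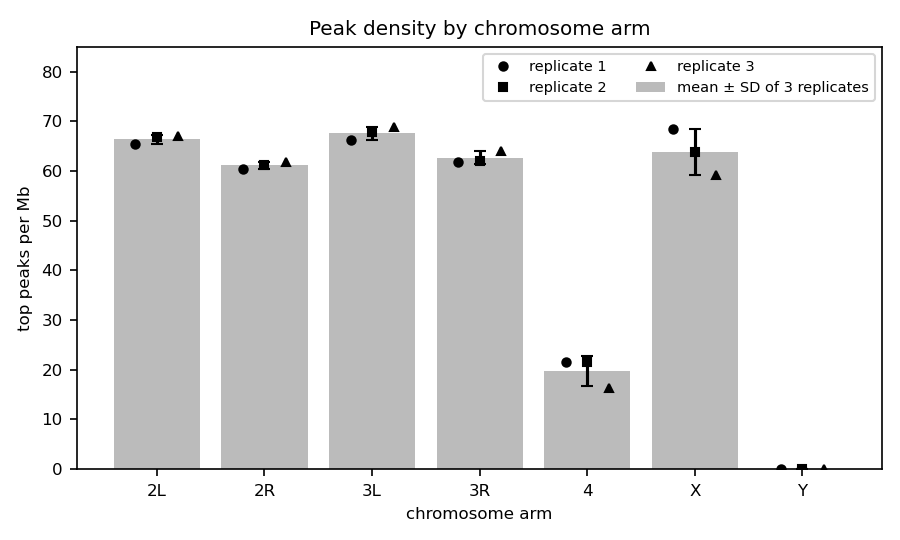
Peaks per Mb on each chromosome arm among the top 8551 peaks of each replicate. Bars are the mean and error bars the SD of 3 replicates, shown as points. Replicates lie close together on the large autosome arms and spread from 59.3 to 68.5 on X.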

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

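The shuffled and AT-matched controls, the gene body test and the set of peaks with the lower signal were chosen after seeing the data. The promoter share stayed above that of the relaxed entries outside the optimal list, which may include background, under all 7 alternatives run. The dm3 lists gave 8497 peaks and 73.6% sharing, but the X to autosome ratio on dm3 was not run because arm lengths of that build were not used here. With the 4275 peaks of higher signal, 2538 genes had a promoter peak, and 2 lists were enriched. Sharing between replicates was 61.3% at 50 bp, 80.4% at 200 bp, 82.1% for intervals sharing 1 bp, 79.9% with the top 4275 peaks per replicate and 64.5% with lists of doubled length; a wider match shares more by construction, and the cause of the change with list length was not tested. Leaving out a replicate leaves a single pair, so this setting only repeats the pair values of sharing given above, from 72.5% to 77.1%. Against genes with a relaxed peak at the promoter, 1 list was enriched and 4 depleted; this background has fewer genes. In the gene body test 2 lists were enriched and 2 depleted, and in the peaks with the lower signal 2 enriched and 4 depleted; the cause was not tested. The X to autosome ratio per protein-coding gene was 1.17, since X has fewer such genes per Mb. Against shuffled windows 16 words were enriched, and the Homeodomain word turned to a ratio of 0.818; against AT-matched windows its ratio was 0.980 and it was not called. Of the depleted words, GAGAGAG, GAGAG, the CA repeat, Su(H) and Grainyhead turned to ratios above 1. They were at 2.77, 1.41, 4.21, 1.38 and 5 against shuffled and 2.58, 1.29, 1.43, 1.06 and 2.5 against AT-matched windows. Su(H) and Grainyhead were not called in either. CACGTG and Zelda also lost their calls in both, at 0.723 and 0.8 against shuffled and 0.986 and 0.865 against AT-matched windows. No depth is known, so its limits cannot be given.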

Other observations

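The tests in this part were chosen after the results were seen, except the word comparison without promoter peaks, which was planned before the data were examined. For that comparison, the number of words expected to stay enriched was written after its result was seen. The shuffled and AT-matched controls were added after the comparison with flanks was seen, with the expected number of words that stay enriched written before their own results; what was expected of the DRE word was written after its result was seen.

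Ecdysone response genes were enriched when peaks in the gene were counted. At promoters they had a peak at 45.7% against 28.9% of other genes, not called, but within 1000 bp of a start they were called (62.9%, exact test, adjusted p = 0.00136), and the settings were not tested against each other. An optimal summit lay in 21 of 35 of these genes (60.0%), against 37.3% of random genes matched on length (permutation test with 10000 draws, adjusted p = 0.0186 over 31 lists), and the 35 genes held 113 summits. The genes with the most, named after their values were seen, were Eip75B with 26, which encodes a nuclear receptor, EcR with 16, the ecdysone receptor gene, and Eip74EF with 11, an ETS factor gene. These are long genes, of 113744, 81215 and 60654 bp. The test matched on length was of the presence of a summit, so the summit counts are not adjusted for length. Ribosomal protein genes were enriched in the same test (27.7% against 6.23%, permutation test, adjusted p = 0.00207). The test counted summits anywhere in the gene, those within 500 bp of a start included. It therefore shares peaks with the promoter test and is not separate support for it. Neuronal genes (22.0% against 46.1%) and receptor genes (0.873% against 8.51%) were depleted, each at adjusted p = 0.00207 in the permutation test. That value is the smallest the draws gave over these lists. Other genes rich in summits, also named after their values were seen, were the long adhesion gene kirre on X with 36 over 394149 bp, sbb with 26, Tet with 22, CG1677 with 21, and shn and ush with 20 each.

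X-linked peaks ranked lower in replicate 3 than in replicate 1, and so did the 20 peaks of chromosome 4, at -7.96 points of percentile rank relative to the large autosome arms, with no interval computed. Over 1413 X-linked peaks found in both relaxed lists, the median change in percentile rank was -2.54 points relative to the autosome arms. The 95% bootstrap interval was -3.40 to -2.0 and does not cover variation between replicates. The change was -1.07 for replicate 2 against 1 and -1.34 for 3 against 2. It thus does not rest only on peaks absent from either relaxed list. A peak leaves the top list by falling in rank, so entering or leaving that list was not tested apart. Compared with autosomal peaks of the same GC content the change was -2.77 points (-3.60 to -2.26), which argues against GC content. An even shift of the whole chromosome, as unequal numbers of X copies in the pooled larvae would give, may be part of it, but only 2 of 4 equal parts of X, by number of peaks, had an interval that held -2.54, and the parts differed (permutation test within 10 rank bins, p = 0.0006, with neighbouring peaks not independent). In the relaxed lists of 30000 entries, which may include background, X held 19.6%, 18.3% and 15.8% in replicates 1, 2 and 3. The lower share of X was thus not confined to the top lists, and an even shift is left open. The makeup of the pools by sex is not known here, and no biological explanation was tested.

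The enriched words may largely follow the AT-rich sequence at summits. In the test of AT content of the summit windows, for most of the words the call was lost: 4 of the 9 stayed enriched against genomic windows of equal AT content, and TATA, Homeodomain, Ohler motif 6, Su(Hw) and the A run did not. For the DRE word AT content is argued against, at a ratio of 7.0 to such windows, though these lie over 1000 bp from any relaxed summit and 3 words depleted at summits were enriched against them as well. Without promoter peaks 7 of 9 words stayed enriched over flanks, DRE and Ohler motif 7 being the exceptions. This argues against promoter position for the enrichment of most words over flanks. The 7 include the words just named that lost their call against windows of equal AT content. Of the 4 words kept against those windows, only Forkhead and M1BP stayed enriched without promoter peaks, so promoter position is not argued against for the 4 as a set. For M1BP the call without promoter peaks rests on few windows, 15 with the word only at the summit against 3 only at the flank. M1BP was at 0.322% of these summits and 2.90% of promoter summits, so promoter position is left open for it. Against shuffled windows 7 of 9 stayed enriched, which met the outcome written in advance against base composition, but the same 3 depleted words were enriched there too and the 2 controls disagreed on Ohler motif 6, Su(Hw) and the A run, so base composition is left open, a reading chosen after the result was seen.

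Extra copies of the rgr region carried by the transgene may add to the peaks in rgr. The gene held 12 relaxed summits, above the 95th percentile of 9 for the 564 genes of similar length, of which 13 (2.30%) had at least as many. A count above that percentile was part of the outcome written for extra copies, but whether extra copies add separate summits was not tested. The outcome written for extra copies, after the counts were seen, also had the optimal share of these peaks at or below the genome-wide share, and it was higher, 50% against 28.5%. That share does not decide, since extra copies could raise the signal of peaks as well. Extra copies and binding at the gene's own locus cannot be told apart, because peak lists show no copy number.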
